A study of Mus musculus with 6 samples.

How the data were processed

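The series profiled astrocytes that had been sorted from the central nervous system of female C57BL/6 mice, 12 to 13 weeks old, in which experimental autoimmune encephalomyelitis (EAE) had been induced. EAE is a mouse model of multiple sclerosis in which immunisation against a myelin peptide brings immune cells into the brain and spinal cord. Per the labels' protocols, each mouse received 150 µg of the myelin oligodendrocyte glycoprotein peptide MOG 35-55 in 100 µL of saline emulsified in 100 µL of complete Freund's adjuvant. Per the labels' protocols, each central nervous system was digested with papain, passed through a 70 µm filter and spun in 30% Percoll, and astrocytes were then sorted by negative selection, that is, by leaving out cells that carry markers of other types. Libraries were made with Smart-seq2, a full-length cDNA method that starts from little RNA and carries no molecular identifiers, so intervals and counts cover counting error only and not the amplification of single molecules.

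Samples were grouped by the guide named in their labels: 3 libraries labelled sgScrmbl (a scrambled control guide) and 3 labelled sgLamp1 (a guide against Lamp1), each from a separate mouse per the labels. Replicate numbers were given in accession order and only name the libraries. The labels give no batch and no pairing. How the guides were delivered and which part of the gene the Lamp1 guide targets are not given in the sources used here.

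The authors deposited, for each library, kallisto output with an estimated count, a TPM value (transcript abundance scaled to a fixed total) and an effective length for each of 142351 GENCODE mouse transcripts. Per the submitters' processing notes, kallisto 0.46.1 was used with genome build GRCm38, and per the deposited run records no bootstraps were drawn (0) and no strand option was set, so reads of overlapping or antisense genes cannot be told apart. The deposited estimated counts are not whole: kallisto divides reads that fit several transcripts between them, which makes counts of near-identical paralogs and gene families uncertain. The run records give between 9509825 and 13568888 read pairs per library, of which between 3113027 and 6199168 were pseudoaligned. A second abundance table per library held the same estimated counts to within a relative difference of 4.86e-06 apart from 15 emptied lines, and was not used further.

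From there, estimated counts were summed over the transcripts of each of 55335 genes and rounded to whole numbers. Of the gene identifiers, 55154 were found in GENCODE release M21 (GRCm38), from which biotypes and coordinates were taken; symbols are those of the deposited files, and 1512 of them differ from M21. The authors' GENCODE release is not given in the sources used here. Deposited TPM values were summed per gene and used only for levels within a library. For this they were rescaled to a fixed total without the satellite-like, mitochondrial and ribosomal RNA models, and hemoglobin genes stayed in. A family of 12 satellite-like gene models was defined as those sharing at least 40% of their 31-base words with 4 seed models, Gm10800, Gm10801, Gm10719 and Gm10718. Gene models that collect ribosomal RNA reads (AY036118, CT010467.1, Gm26917, Lars2 and annotated rRNA genes) were set apart as ribosomal RNA loci. Shares of counts in single libraries carry 95% Wilson intervals, which reached at most 0.0467 percentage points to either side.

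Differential expression was tested with edgeR 4.0.16 (R 4.3.3): filterByExpr by group, TMM normalisation, robust quasi-likelihood fits and F tests, with Benjamini-Hochberg adjustment at 0.05. All adjusted p values of single genes come from this test unless another tool is named. Standard errors were taken from the fold change and its F statistic. Gene lists, 26 of cell states and 13 of cell type markers, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists with at least 4 tested members were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, two-sided, adjusted over all lists. The same lists were tested with a correlation estimated per list and with fry. Values of single measures were compared by exact two-sided permutation tests, for which 3 libraries against 3 allow no p below 0.1.

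The rule for named genes took Lamp1; then, among protein-coding genes past 0.05 with a symbol other than a Gm or Rik model, a mean of at least 5 CPM in the higher group and no overlap between groups, the 12 largest changes in each direction, or, with fewer than 3 such genes, the 10 with the smallest unadjusted p in each direction; then the 3 members with the smallest p of each list past the threshold and at most 2 of each other state list; always Tnfsf10, Lamp2, Gfap, Aqp4, Aldh1l1, Slc1a3 and Sox9; and the most abundant member of each cell type list. Some genes that the rule takes are not reported here. Leaving out the library labelled sgScrmbl replicate 1 was one of the alternatives fixed beforehand. Giving the fit of the other 5 libraries its own paragraphs, applying the naming rule to it and repeating all alternatives on it were chosen after seeing that library's content. In that fit, genes with 1 to 3 counts over the 2 control libraries are given as ratios of normalised counts with exact 95% intervals.

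Alternatives were median-ratio (RLE) and upper-quartile factors, no filter on low counts, a filter of 5 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom with quality weights, an offset for average transcript length, protein-coding genes without mitochondrial genes and rRNA, and leaving out each library. Restricting to protein-coding genes outside Gm, Rik and mitochondrial models was added after seeing the data. The pipeline was tested on simulated counts drawn from these libraries, with 200 genes changed. In the simulation of the 6 libraries, over 14945 genes, 0% of the 2-fold and 0% of the 8-fold changes were called, and the median estimates were 0.83 and 3.25 on the log2 scale, where the true values were 1 and 3. In the simulation of 5 libraries, over 15978 genes, 13% of the 2-fold and 97% of the 8-fold changes were called, with median estimates of 1.05 and 3.19, and 15 unchanged genes were called. With 100 genes changed per fold, the share of false calls there was above the 0.05 threshold. For the list test, the 28 type I interferon genes were shifted in the simulation of 5 libraries and had an adjusted p of 1.34e-17, against 0.0518 in the simulation of 6, and none of the lists left unshifted was called. Simulated genes were drawn independently of each other, so this part does not test how the preset correlation fits real genes. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 built the gene tables and figures.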

Results

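RNA-seq libraries were available from sorted astrocytes of 6 mice with EAE, 3 labelled with a scrambled guide (sgScrmbl) and 3 with a guide against Lamp1 (sgLamp1). Lamp1 encodes a heavily glycosylated protein of the lysosomal membrane that also marks the cell surface after lysosomes fuse with it. The question put by the series is how the transcriptome of astrocytes with lowered Lamp1 differs from that of control astrocytes during EAE. The pseudoaligned read pairs numbered 3113027, 6199168 and 4379205 in the libraries labelled sgScrmbl replicates 1 to 3, and 5414650, 4708008 and 4808250 in those labelled sgLamp1 replicates 1 to 3.

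Much of each library fell on a repeat-like sequence rather than on expressed genes. A family of 12 satellite-like gene models on chromosomes 2, 9 and 14, among them Gm10800 (chromosome 2, 98666547 to 98667301, GRCm38), took 74.95% ± 4.06 (SD, n = 3) of the estimated counts in the libraries labelled sgScrmbl and 48.4% ± 10.4 (SD, n = 3) in those labelled sgLamp1. The exact permutation p was 0.1, the smallest that 3 against 3 allows. Hemoglobin genes, which are transcripts of red blood cells and their precursors, took 0.000450%, 0.9505% and 1.81% in replicates 1 to 3 labelled sgScrmbl and 11.97%, 9.26% and 2.23% in those labelled sgLamp1. The exact permutation p was again 0.1 (n = 3 and 3), and the library labelled sgLamp1 replicate 3 lay close to sgScrmbl replicate 3. Protein-coding genes outside Gm, Rik and mitochondrial models, hemoglobin genes and Lars2 included, received 658775 ± 342479 counts (SD, n = 3) in the libraries labelled sgScrmbl. They received 1.77e+06 ± 6.04e+05 (SD, n = 3) in those labelled sgLamp1, with an exact permutation p of 0.1. Without hemoglobin genes and ribosomal RNA loci, the counts were 263744, 772647 and 789632 in replicates 1 to 3 labelled sgScrmbl. In those labelled sgLamp1 they were 1784826, 1148618 and 1156805.

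The library labelled sgScrmbl replicate 1 stood apart from all others. It held 263798 counts on these protein-coding genes and 4939 protein-coding genes with at least 10 counts, against 10744 to 13251 such genes in the other 5 libraries. Clu and Glul, both abundant in astrocytes, had 0 counts in it, as did the endothelial gene Cldn5 and the mural cell gene Vtn, and Slc1a3 had 31. Across genes, its log2 CPM values correlated with those of the other libraries at Pearson's r between -0.01 and 0.20, whereas the pairs among the other 5 libraries lay between 0.83 and 0.92 (genes are not independent replicates). Ttr, the thyroxine carrier made by choroid plexus epithelium, had 3 counts in it and between 23446 and 85964 in the others.

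**Figure D1:**
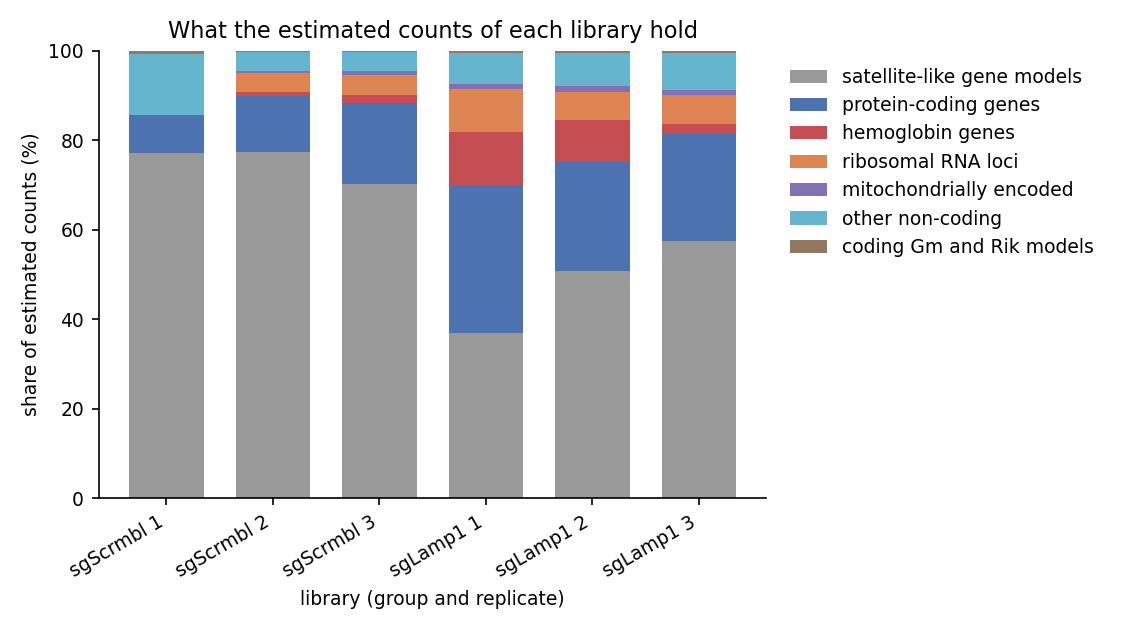
Stacked bars give the share of estimated counts (%, y axis) by class of gene for each of the 6 libraries (x axis, guide label and replicate). Satellite-like models average 74.95% in the libraries labelled sgScrmbl and 48.4% in those labelled sgLamp1, and the library labelled sgScrmbl replicate 1 shows almost no hemoglobin or ribosomal RNA counts.

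Lamp1 RNA was not lower in the libraries labelled sgLamp1. Lamp1 (ENSMUSG00000031447, GRCm38 chromosome 8, 13159161 to 13175338, plus strand, 2 annotated transcripts) had 1, 206 and 307 counts in the libraries labelled sgScrmbl and 733, 429 and 708 in those labelled sgLamp1. In normalised counts this was 41.5 ± 37.7 CPM (SD, n = 3) against 90.4 ± 19.7 CPM (SD, n = 3), a log2 fold change of 1.12 (SE 1.31, adjusted p = 0.997), with an exact permutation p of 0.2. Without the library labelled sgScrmbl replicate 1, the levels were 69.4 ± 19.8 CPM (SD, n = 2) and 100.5 ± 21.7 CPM (SD, n = 3), a log2 fold change of 0.53 (SE 0.35, 95% interval -0.19 to 1.26, adjusted p = 0.571). The exact permutation p of those 5 libraries was 0.3, where the smallest possible is 0.1. Nearly all counts lay on the protein-coding transcript Lamp1-201, and the retained-intron transcript Lamp1-202 had at most 3.30 in any library. A guide that disrupts the coding sequence need not lower the RNA, so Lamp1 RNA alone does not check the labels, but it goes against the direction that the abbreviation KD (knockdown) in the series title implies. The guide names are therefore used as labels throughout.

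Lamp2, the closest relative of Lamp1, and Tnfsf10, which encodes the death ligand TRAIL, did not differ past the threshold either. Without the library labelled sgScrmbl replicate 1, Lamp2 stood at 66.7 ± 1.25 CPM (SD, n = 2) and 84.5 ± 10.8 CPM (SD, n = 3), a log2 fold change of 0.34 (SE 0.32, adjusted p = 0.735). Tnfsf10 stood at 5.82 ± 0.614 CPM (SD, n = 2) and 7.32 ± 2.34 CPM (SD, n = 3), a log2 fold change of 0.32 (SE 0.40, adjusted p = 0.821). Among 16 tested members of the list of death ligands, death receptors and the TRAIL pathway, 0 passed, and the list did not pass either (median log2 fold change 0.31, adjusted p = 0.196). The vacuolar H+-ATPase list (17 members, median 0.13, adjusted p = 0.469) and the autophagy list (35 members, median -0.01, adjusted p = 0.469) did not pass in these 5 libraries. Their medians turned in sign without sgLamp1 replicate 1 (-0.08) and without sgScrmbl replicate 2 (0.01), respectively.

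**Figure D2:**
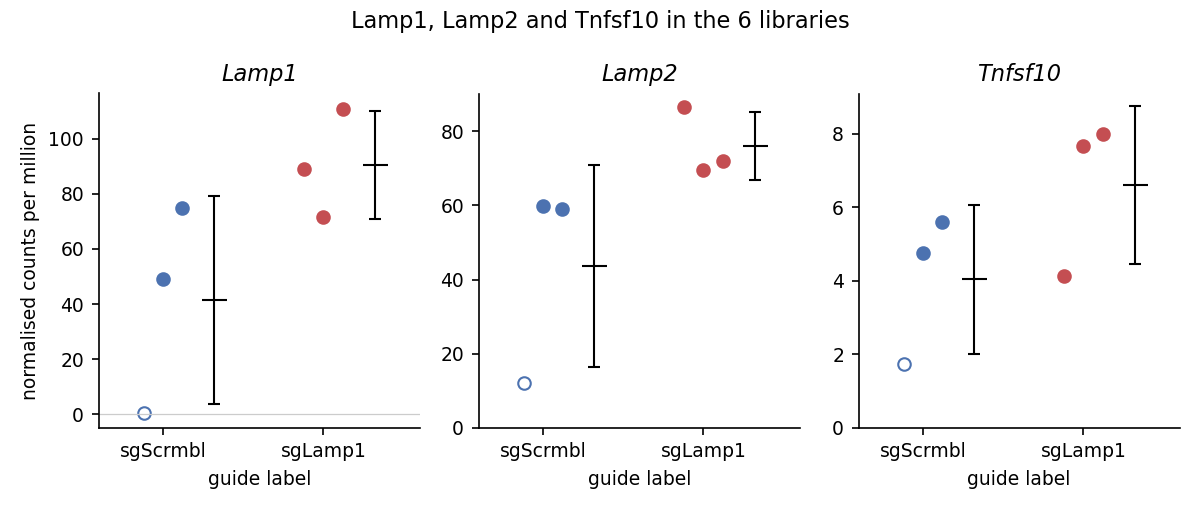
Points give the normalised CPM (y axis, linear) of Lamp1, Lamp2 and Tnfsf10 in each of the 6 libraries by guide label (x axis), the open point is the library labelled sgScrmbl replicate 1, and the bars give the mean ± SD of each group of 3. Lamp1 averages 41.5 CPM in the libraries labelled sgScrmbl and 90.4 CPM in those labelled sgLamp1, with no call.

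With all 6 libraries, 14945 genes were tested and edgeR called 0 higher and 0 lower in the libraries labelled sgLamp1. At an unadjusted p under 0.05 there were 357 genes. DESeq2 called 52 higher and 6 lower, limma-voom 0 (1811 at an unadjusted p under 0.05), and edgeR without a filter on low counts 66 higher and 36 lower. Leaving out the library labelled sgScrmbl replicate 1 changed the edgeR counts to 127 and 82. The genes with the smallest unadjusted p were not past the threshold (adjusted p = 0.997 each). Among those with higher values were Hcar2, the receptor for hydroxybutyrate and niacin on myeloid cells (log2 fold change 4.62, SE 0.78), Cst7, a cystatin of activated myeloid cells (4.30), and Acod1, which makes itaconate in activated macrophages (2.97). Bcl2a1d, from a family of near-identical copies that kallisto may not separate, had 3 control counts and a ratio of 48.8 (95% counting interval 16.5 to 238), and Mgl2, a macrophage lectin, also had 3 and a ratio of 44.4 (15.04 to 217). Among those with lower values were Gpc5, a heparan sulfate proteoglycan of astrocytes (log2 fold change -1.89), Astn1 (-1.53), Nrcam, a neuronal and glial adhesion molecule (-1.50), and Rex2 (-4.29), which belongs to a zinc finger cluster with near-identical copies. The groups did not overlap in 11.03% of genes, where chance gives 10%.

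Without the library labelled sgScrmbl replicate 1, 15978 genes were tested, and 127 were higher and 82 lower in the libraries labelled sgLamp1 than in the 2 remaining libraries labelled sgScrmbl. Leaving out a further library moved the counts by over 1.5 times in several cases. They were 509 higher and 146 lower without sgScrmbl replicate 2, 35 lower without sgLamp1 replicate 1, 260 higher without sgLamp1 replicate 2 and 54 lower without sgLamp1 replicate 3. With limma-voom the counts were 32 and 34, with DESeq2 220 and 122, and without a filter on low counts 513 and 145. Of the 209 genes, 59 kept their call with limma-voom, 122 with an offset for transcript length, 87 of 208 without sgScrmbl replicate 3 and 96 of 205 without sgLamp1 replicate 1. Of the 61 called genes that the naming rule took, 23 kept their call with each further library left out and 11 in every setting, among them Cxcl2, Bst2, Ifi27l2a, Ctss, Agt, Grm3, Ncan, Bcan, Fgfr3 and Cspg5. Slc1a2, Spp1, Il1a, Cxcl1 and Ccl2, named below as called members of lists, lie outside the rule and were not followed over these settings.

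Genes that mark astrocytes were lower as a list without the library labelled sgScrmbl replicate 1. Of 24 tested members of the astrocyte identity list, 9 fell and 0 rose, and 20 fell when adjusted over the list alone. The list had a median log2 fold change of -1.27 (adjusted p = 1.06e-17 with the preset correlation, adjusted p = 0.374 with an estimated correlation). Bcan, a proteoglycan of the perineuronal matrix, fell by 1.72 on the log2 scale (SE 0.33, adjusted p = 0.0165), from 140.1 ± 0.598 CPM (SD, n = 2) to 42.6 ± 10.8 CPM (SD, n = 3). Fgfr3, a growth factor receptor of mature astrocytes, fell by 1.61 (SE 0.31, adjusted p = 0.0168), and Ntsr2, a neurotensin receptor, fell by 1.66 (SE 0.32, adjusted p = 0.0170). The call of Ntsr2 was lost without sgScrmbl replicate 3 (adjusted p = 0.0628). Aqp4, the water channel of astrocyte endfeet, fell by 1.51 (SE 0.32, adjusted p = 0.0270). Its call was lost without sgScrmbl replicate 3 (adjusted p = 0.205), sgLamp1 replicate 1 or sgLamp1 replicate 3. The intermediate filament gene Gfap had a log2 fold change of -0.51 (SE 0.37, adjusted p = 0.624) at 11.2 ± 1.64 and 7.88 ± 3.16 CPM (SD, n = 2 and n = 3), and Aldh1l1 (-0.88), Slc1a3 (-1.30) and Sox9 (-1.11) did not pass over all genes (adjusted p = 0.182, 0.0818 and 0.0743). In the 6-library fit the same list did not pass, and Bcan had an unadjusted p of 0.489 there, with a log2 fold change of -1.12.

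The transporters by which astrocytes clear transmitter and buffer ions were lower as a list. It shares 7 of its 16 tested members with the astrocyte identity list. Of 16 tested members of the list of glutamate, potassium and water handling, 6 fell and 0 rose (12 fell when adjusted over the list alone). The median log2 fold change was -1.29 (adjusted p = 1.47e-11 with the preset correlation, adjusted p = 0.374 with an estimated correlation). The GABA transporter gene Slc6a11 fell by 1.72 (SE 0.33, adjusted p = 0.0165), the potassium channel gene Kcnj10 fell by 1.43 (adjusted p = 0.0366, but 0.112 without sgLamp1 replicate 1, and lost too without sgScrmbl replicate 3) and the glutamate transporter gene Slc1a2 fell by 1.67 (adjusted p = 0.0358). The call of Slc6a11 was lost without sgScrmbl replicate 3 (adjusted p = 0.0580). In the list of extracellular matrix and scar genes, 3 of 23 members fell and 1 rose (median -0.74, adjusted p = 6.75e-06, adjusted p = 0.374 with an estimated correlation). The members that fell were the brain proteoglycans Ncan (-1.86), Cspg5 (-1.69) and Bcan, and the one that rose was Spp1 (1.65), a secreted protein that microglia and macrophages also make. Beside these lists, markers of mural cells and fibroblasts (10 members, median -0.88, adjusted p = 0.000165) and of oligodendrocytes (8 members, median -0.92, adjusted p = 0.0111) were lower as lists too, with 0 members past the threshold in either. Both lost the call with an estimated correlation (adjusted p = 0.374 each).

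Genes of inflammatory signalling were higher as a list in the same 5 libraries. Of 25 tested members of the list of NF-kB targets, cytokines and chemokines, 8 rose and 0 fell (15 rose when adjusted over the list alone). The median log2 fold change was 1.46 (adjusted p = 7.52e-12 with the preset correlation, adjusted p = 0.374 with an estimated correlation). The neutrophil chemoattractant gene Cxcl2 rose by 2.70 (SE 0.39, adjusted p = 0.00442), from 3.91 ± 2.08 CPM (SD, n = 2) to 25.6 ± 4.63 CPM (SD, n = 3). The NF-kB feedback inhibitor gene Tnfaip3 rose by 1.93 (SE 0.36, adjusted p = 0.0165) and the prostaglandin synthase gene Ptgs2 by 2.28 (SE 0.43, adjusted p = 0.0165). The other members past the threshold were Cxcl10, Il1a, Cxcl1, Tnfaip2 and Ccl2. Without sgScrmbl replicate 3 the calls of Tnfaip3 (adjusted p = 0.0789), Cxcl10 (adjusted p = 0.0709) and Tnfaip2 were lost, that of Tnfaip2 also without sgLamp1 replicate 1 (adjusted p = 0.0871) or 3.

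Interferon-inducible genes were higher in both of their lists. In the type I interferon list, 5 of 28 members rose and 0 fell (15 adjusted over the list alone), with a median of 1.02 (adjusted p = 1.47e-11, adjusted p = 0.374 with an estimated correlation). The members were Bst2, Ifi27l2a, Irf7, Zbp1 and Trim30a, and the calls of Zbp1 and Trim30a were lost in several fits with a library left out. Bst2, which tethers virions to the cell surface, rose by 2.01 (SE 0.34, adjusted p = 0.00986), Ifi27l2a by 2.79 (SE 0.52, adjusted p = 0.0284) and the transcription factor gene Irf7 by 1.55 (adjusted p = 0.0356, but 0.109 without sgScrmbl replicate 3, and lost too without sgLamp1 replicate 1). In the list of interferon-gamma-induced GTPases and chemokines, 4 of 19 members rose (11 adjusted over the list alone), with a median of 1.23 (adjusted p = 5.59e-11, adjusted p = 0.374 with an estimated correlation). Among them were Gbp3 (1.42) and the MHC class I activator gene Nlrc5 (1.75). Their calls were lost without sgScrmbl replicate 3 (adjusted p = 0.208 and 0.279) and without sgLamp1 replicate 1, that of Gbp3 also without sgLamp1 replicate 2 and that of Nlrc5 without sgLamp1 replicate 3. In the list of MHC class I presentation 3 of 17 rose (10 adjusted over the list alone; median 0.94, adjusted p = 1.02e-06, adjusted p = 0.376 with an estimated correlation). These were H2-Q7 (2.17), one of a family of similar genes, and the immunoproteasome genes Psmb8 (1.71) and Psmb9 (1.93). All 3 calls were lost without sgScrmbl replicate 3 (adjusted p = 0.0644, 0.103 and 0.147), and those of Psmb8 and Psmb9 also without sgLamp1 replicate 1. In the list of MHC class II presentation 1 of 8 rose, Ctss (3.10), the cathepsin that trims the invariant chain (median 3.05, adjusted p = 3.13e-08, adjusted p = 0.374 with an estimated correlation). The median of the class II list was 4.53 without sgScrmbl replicate 2, 2.32 without sgScrmbl replicate 3 and 2.31 without sgLamp1 replicate 1. In the complement list 2 of 14 members rose, C1qb and C1qc (2.44 and 2.52; median 1.011, adjusted p = 0.000518, adjusted p = 0.376 with an estimated correlation). Both calls were lost without sgLamp1 replicate 1 (adjusted p = 0.108 for C1qc), and that of C1qb also without sgScrmbl replicate 3 (adjusted p = 0.0997). The complement list's median was 1.98 without sgScrmbl replicate 2.

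Marker lists of leukocytes and red cells were also higher in the 5 libraries, though not each marker in each library. Of 10 microglial markers, 2 rose, among them Trem2, a lipid receptor of microglia (2.42, adjusted p = 0.0168), and the list median was 1.35 (adjusted p = 4.51e-06, adjusted p = 0.376 with an estimated correlation). The monocyte and macrophage list (12 members, 0 past the threshold, median 1.81) had an adjusted p of 4.45e-07, and the adjusted p = 0.376 with an estimated correlation. Lyz2, its most abundant member, stood at 43.5 ± 44.6 CPM (SD, n = 2) and 586 ± 417 CPM (SD, n = 3), with an adjusted p of 0.289. In the T and NK cell list 1 of 11 rose, Cd3e, a chain of the T cell receptor complex (2.71, adjusted p = 0.0484, but 0.164 without sgLamp1 replicate 1, and lost too without sgScrmbl replicate 3; list median 2.28, or 2.19 with 2 members of 3 or fewer counts set to the bound nearest to 0; adjusted p = 5.50e-07, adjusted p = 0.376 with an estimated correlation). The B and plasma cell list (6 members, median 3.66, or 1.80 with 4 such members at their bound; adjusted p = 0.000346), the dendritic cell list (6 members, median 1.89, adjusted p = 0.000142), the neutrophil list (8 members, median 0.52, adjusted p = 0.00805) and the erythroid list (5 members, median 1.73, adjusted p = 0.00664) were higher with 0 members past the threshold. With an estimated correlation their adjusted p values were 0.376, 0.374, 0.539 and 0.437. Without sgScrmbl replicate 2 the medians of the microglial, monocyte, T and NK cell and neutrophil lists were 2.40, 2.78, 2.89 and 3.09. Without sgScrmbl replicate 3 the microglial median was 0.71 and that of the B and plasma cell list 2.74, and without sgLamp1 replicate 1 the T and NK cell median was 1.10 and the dendritic cell median 1.18. The B and plasma cell list's median was 6.65 without sgScrmbl replicate 2, and only 2 of its members were tested without sgLamp1 replicate 1 or 3 (medians 1.035 and 2.04). In the lymphocyte lists the library labelled sgLamp1 replicate 1 held the highest levels of several genes. The antibody chain gene Jchain stood there at 76.9 CPM and at 1.11 and 6.58 CPM in the other 2 labelled sgLamp1, and the cytokine receptor gene Il2rb at 35.1, 2.96 and 7.44 CPM. The neutrophil list turned direction without sgScrmbl replicate 3 (median -0.40, adjusted p = 0.287). In it S100a9, Camp and Ngp had negative values, with their highest levels in sgScrmbl replicate 2. Of the red cell genes, Hba-a2 stood at 8914 and 10450 CPM in the libraries labelled sgScrmbl and at 44230, 40200 and 9567 CPM in those labelled sgLamp1. The erythroid list had an adjusted p of 0.125 without sgScrmbl replicate 2. Endothelial (10 members, median -0.29, adjusted p = 0.186), oligodendrocyte precursor (6 members, median -0.19, adjusted p = 0.293), neuronal (6 members, median -0.56, adjusted p = 0.136) and ependymal and choroid plexus markers (8 members, median 0.13, adjusted p = 0.927) did not pass as lists. Without sgScrmbl replicate 3 the endothelial, neuronal and ependymal medians turned in sign (0.27, 0.07 and -0.04).

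**Figure D3:**
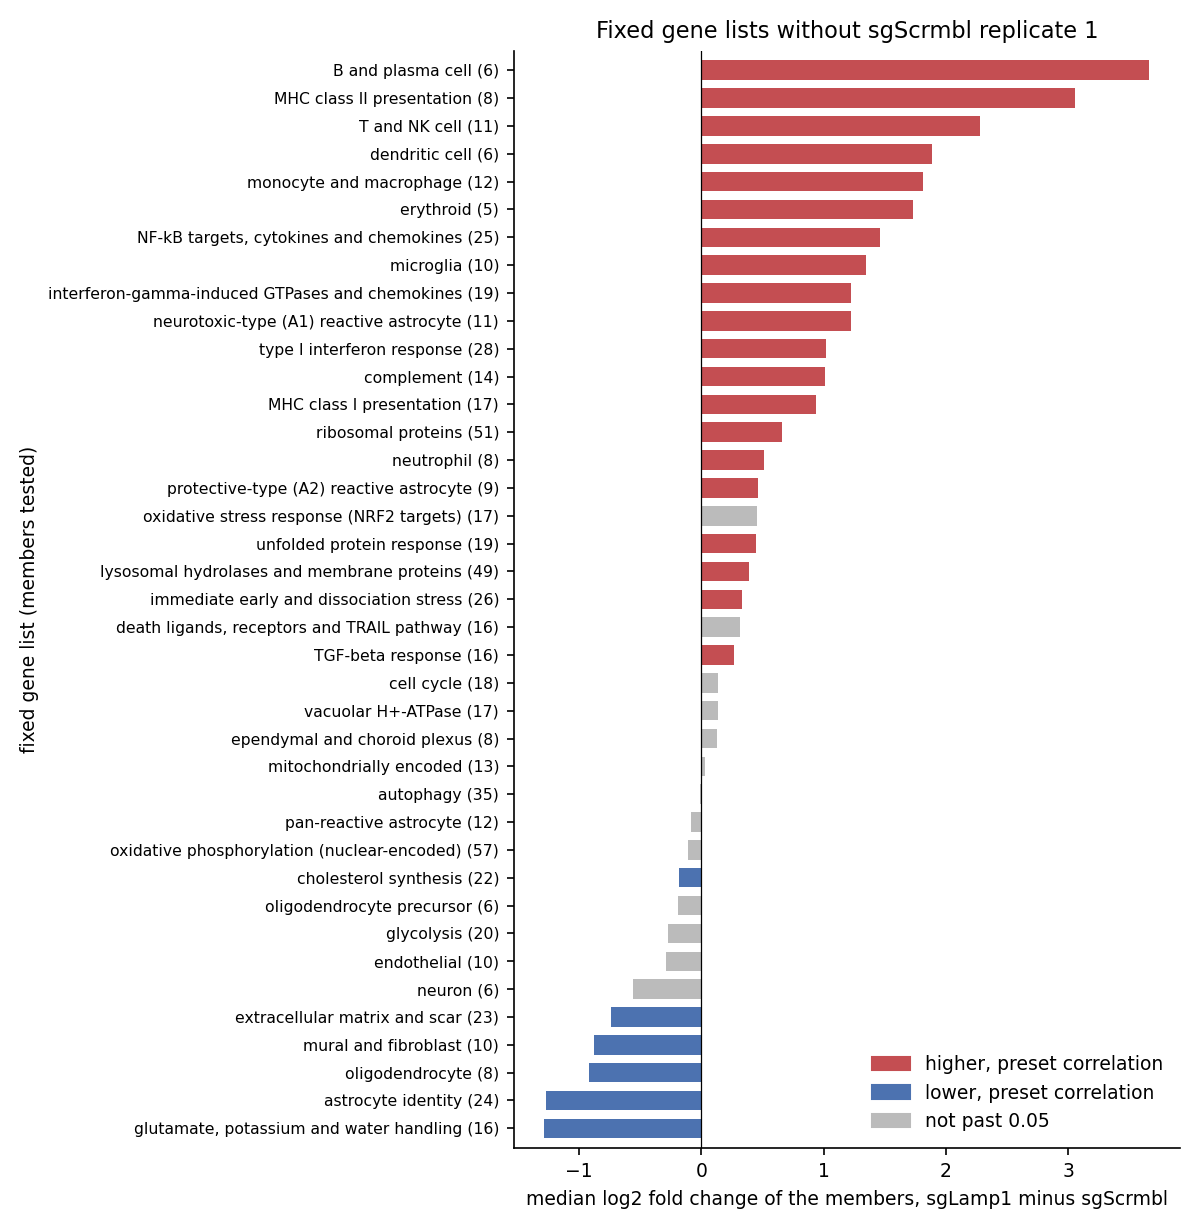
Bars give the median log2 fold change (x axis, sgLamp1 minus sgScrmbl) of the tested members of each of the 39 fixed gene lists (y axis, members tested in brackets) without the library labelled sgScrmbl replicate 1, coloured by camera's call with the preset correlation. The B and plasma cell list has a median of 3.66 (1.80 with its 4 members of 3 or fewer counts at their bound) and the glutamate, potassium and water handling list one of -1.29, and 0 lists pass with an estimated correlation.

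Of the 3 reactive-astrocyte lists, 2 were higher in the 5 libraries. They are not independent of the lists above. Psmb8, H2-D1 and H2-T23 are also in the MHC class I list, Gbp2 and Iigp1 in the interferon-gamma list and Ptgs2 in the NF-kB list. In the list described for neurotoxic-type (A1) astrocytes, 2 of 11 members rose, the proteoglycan core gene Srgn (1.77) and Psmb8 (1.71), both of which leukocytes also express (6 rose when adjusted over the list alone; median 1.23, adjusted p = 3.36e-05, adjusted p = 0.374 with an estimated correlation). In the protective-type (A2) list, Ptgs2 and the lipopolysaccharide co-receptor gene Cd14 (2.70) rose among 9 members (median 0.47, adjusted p = 0.0263, adjusted p = 0.374 with an estimated correlation). The call of Srgn was lost without sgScrmbl replicate 3 (adjusted p = 0.0644), and that of Cd14 without sgLamp1 replicate 1 or 3 (adjusted p = 0.0795 for the latter). The median of the A2 list was 1.41 over 7 tested members without sgLamp1 replicate 3. The pan-reactive list did not pass (12 members, adjusted p = 0.635; its median of -0.09 and its test differ in sign, and the median was 0.15 without sgLamp1 replicate 1 and 0.02 without sgScrmbl replicate 3). Cxcl10 rose in it by 2.18 (SE 0.42, adjusted p = 0.0191), a call lost without sgScrmbl replicate 3 as above. Among 49 lysosomal hydrolases and membrane proteins other than Lamp1, 2 rose, among them Ctss, which is abundant in microglia (9 rose when adjusted over the list alone; median 0.39, adjusted p = 0.000624, adjusted p = 0.539 with an estimated correlation). The microglial, monocyte and T cell marker lists were higher in the same comparison.

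Lists of general cell functions had medians between -0.27 and 0.66. Among the genes of the TGF-beta response, 1 of 16 rose, Tgfbi, a secreted matrix protein that macrophages also make (1.84, SE 0.40, adjusted p = 0.0319, but 0.136 without sgScrmbl replicate 3, and lost too without sgLamp1 replicate 1 or 3; list median 0.27, adjusted p = 0.0334, adjusted p = 0.379 with an estimated correlation). Ribosomal protein genes (51 members, median 0.66, adjusted p = 1.59e-07), immediate early and dissociation stress genes (26 members, median 0.33, adjusted p = 0.0251) and genes of the unfolded protein response (19 members, median 0.44, adjusted p = 0.0263) were higher as lists, with 0 members past the threshold by edgeR. With an estimated correlation the adjusted p values were 0.539, 0.376 and 0.665. Cholesterol synthesis genes were lower as a list, with 0 of 22 past the threshold (median -0.18, adjusted p = 0.0337, adjusted p = 0.374 with an estimated correlation). The list tests were not past the threshold for nuclear-encoded oxidative phosphorylation (57 members, median -0.11, adjusted p = 0.0568), glycolysis (20 members, median -0.27, adjusted p = 0.161), NRF2 targets (17 members, median 0.46, adjusted p = 0.136) and the cell cycle (18 members, median 0.14, adjusted p = 0.635). Mitochondrially encoded genes did not pass either (13 members, adjusted p = 0.832), and their median of 0.03 and their test differ in sign. With 1 library left out 3 of these medians turned in sign: oxidative phosphorylation (0.05 without sgScrmbl replicate 3), the cell cycle (-0.04 without sgLamp1 replicate 1) and the mitochondrially encoded genes (-0.07 without sgScrmbl replicate 2 and -0.17 without sgLamp1 replicate 2).

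The 12 largest increases and 12 largest decreases of the 5 libraries were taken by the naming rule. Hcar2 (ENSMUSG00000045502, chromosome 5, 123863570 to 123865499) rose from 0.541 ± 0.00378 CPM (SD, n = 2) to 11.02 ± 2.11 CPM (SD, n = 3), a log2 fold change of 4.29 (SE 0.55, adjusted p = 0.0016). Its control level rests on the same few counts in each library, so that SD reflects library size and not the spread between mice. Bcl2a1d and Wfdc17 each had 3 control counts, and their ratios were 40.01 (95% counting interval 13.6 to 195) and 16.0 (5.33 to 78.4). The myeloid or lymphoid genes Clec4n (4.27), Cst7 (3.92), Cd48 (3.91), Gpr183 (3.71), Cd300c2 (3.52), Rhoh (3.48), Fcgr4 (3.404) and Gpr35 (3.21) rose, as did Saa3, an acute-phase protein (3.43, SE 0.47, adjusted p = 0.00303). On the other side, Agt (ENSMUSG00000031980, chromosome 8, 124556534 to 124569706), the angiotensinogen gene that astrocytes express in the brain, fell by 2.00 (SE 0.31, adjusted p = 0.00568), from 35.3 ± 11.5 CPM (SD, n = 2) to 8.77 ± 1.31 CPM (SD, n = 3). Grm3, a metabotropic glutamate receptor, fell by 2.02 (SE 0.34, adjusted p = 0.00986) and the proteoglycan gene Ncan by 1.86 (SE 0.29, adjusted p = 0.00716). The others were Rex2 (-3.74), Fjx1 (-2.27), Eva1a (-2.16), the chemokine gene Cxcl14 (-2.10), Disp3 (-2.06), the myelin glycoprotein gene Omg (-1.79), Igdcc4 (-1.78), Gpc5 (-1.77) and Gpld1 (-1.77). When each of the 5 libraries was left out in turn, 9 of the 12 increases and 3 of the 12 decreases kept their call every time, the latter being Agt, Grm3 and Ncan. The other calls were lost without at least 1 library, up to an adjusted p of 0.102 for the increases (Gpr35, without sgLamp1 replicate 3) and 0.549 for the decreases (Gpc5, without sgScrmbl replicate 3). In every setting, 0 of the 12 increases and the same 3 decreases kept it. With limma-voom none of the increases was called (adjusted p = 0.155 for Hcar2 and 0.381 for Cd48). The groups of 2 and 3 libraries did not overlap in 30.5% of all genes, where chance gives 20%.

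**Figure D4:**
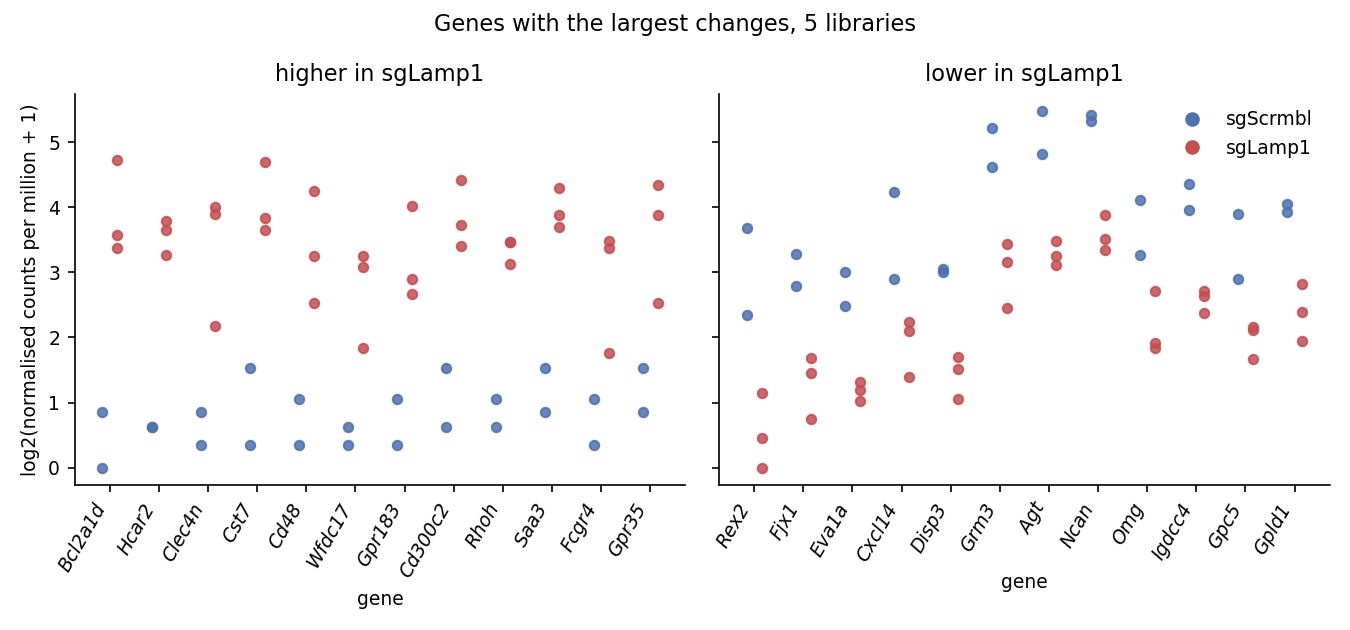
Points give log2(normalised CPM + 1) (y axis) of the 12 genes with the largest increase and the 12 with the largest decrease (x axis) in each of the 5 libraries, coloured by guide label. Agt averages 35.3 CPM in the libraries labelled sgScrmbl and 8.77 CPM in those labelled sgLamp1, and Hcar2 averages 0.541 and 11.02 CPM.

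The fixed lists gave fewer decreases when the library labelled sgScrmbl replicate 1 was kept. With all 6 libraries, 27 of 37 tested lists were higher in the libraries labelled sgLamp1 and 1 was lower, the neuronal markers (median -0.73, adjusted p = 0.0239). The library labelled sgScrmbl replicate 1 held little of most listed genes. Its median TPM for ribosomal protein genes was 1.44, against 332.7 and 399.4 in sgScrmbl replicates 2 and 3. The 27 higher lists therefore do not separate the guide label from the content of that library. Without that library, 20 of 39 were higher and 6 lower. With an estimated correlation 0 lists passed in either fit, the lowest adjusted p being 0.411 with 6 libraries and 0.374 with 5, and fry also called 0, with lowest adjusted p values of 0.266 and 0.150. Against the preset 0.01, the correlations estimated with 5 libraries ranged from -0.08 (pan-reactive) to 0.98 (erythroid), with 0.51 for astrocyte identity. A preset below the true correlation makes the p values of a list too small.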

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

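The alternatives were fixed before the data were examined, except that repeating them on the 5 libraries without sgScrmbl replicate 1 and restricting to protein-coding genes outside Gm, Rik and mitochondrial models were chosen after seeing the data. No paired analysis was possible because the labels carry no replicate numbers. With 6 libraries the edgeR counts of 0 higher and 0 lower genes (357 at an unadjusted p under 0.05; limma-voom 0) became 66 and 36 without a filter on low counts and 52 and 6 with DESeq2. They ranged over 0 to 127 higher and 0 to 82 lower when each library was left out, the upper values without sgScrmbl replicate 1. Lower lists, 1 with 6 libraries, were 0 without a filter, 2 with protein-coding genes, 2 with those outside Gm, Rik and mitochondrial models, and 0 to 6 with a library left out. With an estimated correlation 0 lists were higher and 0 lower, and with fry 0 and 0, with 6 libraries as with 5. With 5 libraries, 127 higher and 82 lower genes became 513 and 145 without a filter, 32 and 34 with limma-voom, 220 higher with DESeq2 and 191 higher with protein-coding genes outside Gm, Rik and mitochondrial models. With a further library left out they ranged over 93 (without sgLamp1 replicate 1) to 509 higher (without sgScrmbl replicate 2) and 35 to 146 lower (the same libraries).

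Without sgScrmbl replicate 1, camera's direction turned against the 6 libraries for 7 lists past the threshold in at least 1 of the 2 fits, and for the endothelial list, which passed in neither. In 3 of the 7 the median kept its sign: extracellular matrix and scar (-0.24 and -0.74), mural and fibroblast (-0.29 and -0.88) and mitochondrially encoded (0.52 and 0.03). Their adjusted p values there, with the other end of their range when a library was left out, were 0.469 for the list autophagy (0.000805), 0.0337 for the list cholesterol synthesis (0.855), 0.0568 for the list oxidative phosphorylation (nuclear-encoded) (1.03e-08), 0.161 for the list glycolysis (3.52e-05), 6.75e-06 for the list extracellular matrix and scar (0.971), 0.832 for the list mitochondrially encoded (0.00603) and 0.000165 for the list mural and fibroblast (0.404). For S100a9, 5 libraries gave a log2 fold change of -0.23, which ranged over -1.16 (without sgScrmbl replicate 3) to 2.80 (without sgScrmbl replicate 2). For the list neutrophil, 5 libraries gave an adjusted p of 0.00805, which ranged over 8.69e-10 (without sgScrmbl replicate 2) to 0.287 (reversed, without sgScrmbl replicate 3). In these fits the single library labelled sgScrmbl was assumed to vary like the others. Without sgScrmbl replicate 2, 3, sgLamp1 replicate 1, 2 or 3, 14, 14, 16, 21 and 17 of the 39 or 38 lists tested were higher, where 5 libraries gave 20, and 9, 4, 8, 6 and 5 lower, where they gave 6. The lists that turned between 6 and 5 libraries did so on leaving out sgScrmbl replicate 1 alone, which held little of them. Its median TPM was 0.755 for mural and fibroblast markers and 1.58 for oxidative phosphorylation, against 124.6 and 237.9 in sgScrmbl replicate 2. For the other reversals and the moved counts the cause was not tested. Of the other results with 5 libraries, 2232 values of named genes and 528 of lists kept their side of the threshold over the alternatives, with the same direction where they passed, 175 and 9 gained a call and 149 and 78 lost it. With 6 libraries these were 1794 and 527 kept, 59 and 12 gained and, for lists, 79 lost. The list test under DESeq2 uses the same log2 CPM and so tests nothing further, and the second abundance table was not run as an alternative because its counts were equal to within 4.86e-06. The simulation of 6 libraries called 0% of 8-fold changes, so a count of 0 there excludes no change of that size. That simulation gave each library the spread estimated with sgScrmbl replicate 1 included (common dispersion 0.476, against 0.0803 without it). It therefore does not mimic 5 similar libraries beside 1 that stands apart.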

Other observations

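The tests of read number, of a lower share of astrocytes alone, of satellite-like counts in the totals and of exchanged labels were chosen after the results they address were seen, and the pan-leukocyte list and the medians with a library left out were added after the data were examined. In the 5 libraries other than sgScrmbl replicate 1, transcripts of vessels and choroid plexus stood beside those of astrocytes in sorted cells. Cldn5, the tight junction gene of brain endothelium, had 1118 and 1968 counts in the libraries labelled sgScrmbl and 2640, 2154 and 1613 in those labelled sgLamp1, where the astrocyte genes Clu and Gfap had 1199 and 1283, and 1710, 1394 and 1006 (Clu), and 46 and 37, and 54, 61 and 29 (Gfap). Ttr reached between 22357 and 26110 TPM in these libraries. Within each library the mural and fibroblast markers had a higher median TPM than the astrocyte identity markers. In the libraries labelled sgScrmbl these medians were 124.6 against 82.6 and 185.1 against 67.0. In those labelled sgLamp1 they were 32.9 against 15.1, 66.2 against 23.1 and 67.9 against 33.9. The hemoglobin gene Hba-a2 alone took 230718 and 231728 TPM in sgLamp1 replicates 1 and 2, so TPM values do not compare the groups.

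The library labelled sgScrmbl replicate 1 held few counts from expressed genes. Too few reads is argued against, since it had 10129448 read pairs where the other 5 libraries had 9509825 to 13568888. A candidate explanation is that its reads came largely from genomic DNA or another background that follows transcript length. Its counts correlated with exonic length at Spearman's rho of 0.519 across protein-coding genes, where the others had 0.430 to 0.483, and with the mean CPM of the other libraries at 0.250, against 0.930 to 0.961. The difference in rho is small and comes from 1 library, so this stays open, as does a failed or nearly empty sort, and no biological explanation was tested.

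Without that library, immune genes were higher and astrocyte genes lower in the libraries labelled sgLamp1. More leukocytes among the sorted cells may account for the immune genes: 15 of 15 pan-leukocyte genes had positive values with a median log2 fold change of 2.02 (interquartile range 1.63 to 2.76; 3.50 without sgScrmbl replicate 2, 1.303 without sgScrmbl replicate 3 and 1.300 without sgLamp1 replicate 1; camera p = 4.54e-12, p = 0.128 with an estimated correlation), although the sort was by negative selection and 1 of 15 passed by edgeR, Tyrobp (2.90). A lower share of astrocytes alone is argued against by a difference in medians. That of 33 leukocyte markers exceeded that of 20 endothelial and mural markers by 2.30 (1.44 to 3.42 with a library left out, the lowest without sgLamp1 replicate 1). The permutation across genes gave p = 1e-05, the smallest possible. Markers of a cell type move together, so this p does not measure the spread between mice. The leukocyte marker lists hold more members than these 33, so the difference does not cover all of them. Their medians ranged from 0.52 (neutrophil) to 3.66 (B and plasma cell, 1.80 with 4 members at their bound). No call that could be tested was lost when satellite-like and mitochondrial counts were left out of the totals, but the number of calls changed. It went from 127 higher and 82 lower to 191 and 98, over 12987 instead of 15978 tested genes. Of the 184 called genes tested among protein-coding genes outside Gm, Rik and mitochondrial models, 100% kept their call and sign (28.2% of all 209 did with limma-voom). TMM already scales for such counts, so that check does not address the fewer counts on expressed genes in the libraries labelled sgScrmbl. A response of astrocytes to the Lamp1 guide stays open. Interferon genes lay below pan-leukocyte genes (difference of medians -0.9997, from -0.27 without sgScrmbl replicate 3 to -2.34 without sgScrmbl replicate 2). The permutation across genes gave p = 0.00034, which again does not measure the spread between mice. Leukocytes express interferon genes too, so the values cannot separate the sources. The real split gave 0 genes with 6 libraries by edgeR (357 at an unadjusted p under 0.05, where another split gave 1024; DESeq2 58, limma-voom 0), as did 10 of 10 splits (highest other 0), and 209 with 5 libraries (1 of 10 splits, highest other 27), and 10 splits are too few for a share under 0.05.

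Lamp1 RNA was not lower in the libraries labelled sgLamp1. One possible explanation is that many Lamp1 reads came from cells that the guide did not target, since nearly all cells express Lamp1. The ratio of endothelial to astrocyte marker median TPM lay between 1.002 (interval from resampling markers 0.192 to 5.25) and 2.68 (0.474 to 21.0) over the 5 libraries, intervals too wide to decide it. A ratio of marker levels also does not measure a share of cells or of Lamp1 reads. It covers endothelial cells only, whose marker list had a median log2 fold change of -0.29 in these libraries. The pan-leukocyte genes had a median of 2.02, and leukocytes as a source of Lamp1 reads were not tested. Exchanged group labels would give a higher Lamp1 value in the libraries labelled sgLamp1, and its log2 fold change of 0.53 (unadjusted p = 0.140) is too uncertain to tell. A guide that alters the protein without lowering the RNA also stays open and was not tested, because the files used here hold no reads.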
